A study of Mus musculus with 10 samples.

How the data were processed

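Liver RNA of 10 male mice was measured on 10 arrays, 5 from mice on a high-fat diet alone and 5 from mice on the same diet with ethanol in the drinking water. Per the labels' protocols, the experiment held 20 mice in 2 groups of 10, and the 5 mice per group used for arrays were picked at random. Each sample is 1 animal. Per the labels' protocols, 150 ng of total RNA was amplified and labelled with Cy3 together with spike-in RNA, giving 6.9 ± 0.7 µg of cRNA and 13.7 ± 0.4 pmol of Cy3 per µg.

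The authors deposited 1 scanner table per array, in which values are spot intensities on a linear scale. Per the file headers they were made with Agilent Feature Extraction 10.7.3.1, from an array designed on the mouse genome build that the headers give as mm9. The processed intensity is the background-subtracted signal of Feature Extraction, and the median intensity and local background of each spot were also used. The authors also deposited 1 table of values on a log2 scale for the 10 arrays. Differences between arrays in it equal those of log2 processed intensity minus each array's 75th percentile (r of 1 for each array over 11027 bright probes). Its column medians were -0.12, 0.08, 0.02, -0.07 and -0.07 for control replicates 1 to 5 and 0.02, -0.0037, -0.01, -0.0020 and 0.05 for ethanol replicates 1 to 5. The value on which each probe was centred stays unknown, but it cancels in every difference between groups. How the authors made this table is not given in the sources used here.

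Control spots and outlier spots were left out. Processed intensities were divided by each array's 75th percentile, values under a floor of 4 signal units were set to 4, and log2 was taken. Spots of 1 probe were averaged. A probe was kept if it was well above background on at least 4 of the 5 arrays of 1 group, which left 31110 of 56605 probes. Gene names came from the RefSeq gene table for GRCm38.p6, through the accession of each probe. Since that build is not the array's, only names were taken from it and no position is given. A single gene symbol was found for 32994 probes, and 23611 were unnamed here and stayed out of the gene tests. Of the unnamed probes 9731 were kept and tested with limma on their own, and 0 passed in either direction, with 1258 at an unadjusted p under 0.05. For a gene with several kept probes, the probe with the highest mean signal was used. Among 5027 such genes, 1780 had probes with fold changes of opposite sign. This left 15088 genes.

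Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) and Benjamini-Hochberg adjustment, with an adjusted p under 0.05 as the threshold. Values of genes are log2 signals relative to the array's 75th percentile, and SE is limma's moderated standard error. The 32 gene lists hold 609 entries, of which 12 had no probe named here. Lists with at least 5 tested genes were tested with camera (preset correlation 0.01), with camera at an estimated correlation and with fry, each adjusted over the lists. The mean of each list per mouse was compared by an exact two-sided permutation test over all 252 assignments of 5 of the 10 mice, for which the smallest possible p is 0.00794.

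The rule for named genes, the lists, the tests and most alternatives were fixed before the data were examined. The rule took up to 15 genes per direction past the threshold with an official symbol and no overlap between groups, for each list up to 4 members past the threshold or, where none passed, the 2 members with the smallest p, and 17 genes named in advance, most of them of ethanol, drug, lipid or bile acid metabolism. The rule took 84 genes, of which 3 list members are not reported here. The alternatives were another normalization, background correction, floor, filter and rule for probes, the authors' deposited log2 values, the slide as a fixed or random block, single slides, a replicate block, other variance models, array weights, and leaving out each array. Normexp on mean spot signals was planned but that column was not used here, and median signals took its place. The array's column as a covariate, the fit without the arrays of slide column 1, the floor of 1, normexp on median signals and the permutation of list means were chosen after seeing the data, as was the count of list members higher or lower under each scaling.

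The 10 arrays lay on 3 slides, as read from the file headers. Slide 1 held control replicates 4 and 5 and ethanol replicate 4, slide 2 held control replicates 1 and 3, and slide 3 held control replicate 2 and ethanol replicates 1, 2, 3 and 5. On each array between 55.5% and 59.1% of spots were well above background, and the 75th percentile of processed intensity ran from 279.9 to 387.4. No pair of arrays was alike enough to be a repeat of 1 sample, as the smallest root mean square difference was 0.301 on the log2 scale.

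The gene and list tests were tested on simulated data with the means and residual SDs of the 15088 genes, 200 genes changed and 5 arrays per group, in 5 simulations with independent noise. Of genes changed 2-fold 76.6% were recovered, and of genes changed 4-fold 95.8%, with 4.65% false among the calls. A list shifted by 0.5 on the log2 scale was found in 5 of 5 simulations. The noise was independent between genes and carried no slide or column structure. In the real arrays the correlation between genes was estimated at 0.842 for the cholesterol list. The simulated rates therefore need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9.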

Results

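Liver gene expression was compared between 2 groups of adult male C57BL/6J mice, an inbred laboratory strain. Both groups ate a high-fat diet for 4 months, and 1 group also drank ethanol in its water during the last 3 months. The intake was 5 g per kg of body weight a day in the first week and 10 g per kg a day afterwards. RNA from 5 mice of each group was hybridised to 1-colour Agilent arrays, with 1 mouse on each array, so n = 5 per group counts animals. On average 57.2% ± 1.33 (SD) of the spots were well above background on the control arrays and 58.0% ± 0.62 (SD) on the ethanol arrays, and no spot was saturated. The number of arrays limits the precision of every value below. The comparison asks how drinking ethanol altered the liver transcriptome of mice already fed a fat-rich diet.

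Of 15088 genes tested, 3 passed the threshold of an adjusted p of 0.05 in limma, 2 higher and 1 lower with ethanol. Hsbp1l1, a relative of a heat shock factor binding protein, was 2.41-fold higher, with a log2 fold change of 1.27 ± 0.13 (SE) and an adjusted p of 0.0164. Its log2 signal relative to the array's 75th percentile was -1.91 ± 0.10 (SD, n = 5) in control and -0.64 ± 0.27 (SD, n = 5) in ethanol livers. Cabp2, which encodes a calcium-binding protein, was 5.99-fold higher, with a log2 fold change of 2.58 ± 0.30 (SE) and an adjusted p of 0.0242. Its probe was well above background on 4 of the 5 control arrays and on all 5 ethanol arrays. Adgrv1, a very large adhesion G protein-coupled receptor, was 4.41-fold lower, with a log2 fold change of -2.14 ± 0.25 (SE) and an adjusted p of 0.0242. The other kept probe of Adgrv1 gave -1.61. For each of these genes the 5 ethanol values lay apart from the 5 control values, as they did for 460 genes in all, or 3.05% of those tested, where chance gives 0.794%. That chance share is an average over all splits of 5 against 5. Genes that vary together can move a single split far from it, so chance is not excluded for the 460 genes. At an unadjusted p under 0.05 there were 2002 genes, 1203 higher and 799 lower with ethanol, against 754 that chance would give if no gene changed. In 6 of 100 splits of the arrays into 5 and 5, the real one included, there were as many, with up to 3603 in another split.

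**Figure D1:**
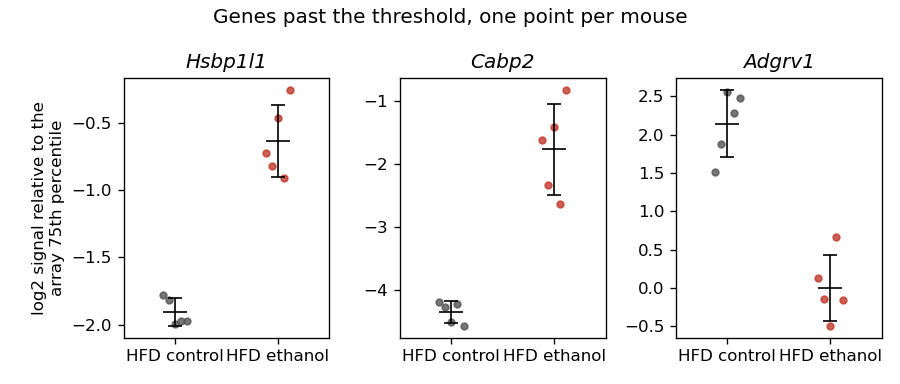
Log2 signal relative to the array's 75th percentile (vertical axis) for Hsbp1l1, Cabp2 and Adgrv1 in control and ethanol mice, with 1 point per mouse and bars for the mean and SD. The 5 ethanol mice lie apart from the 5 control mice in each panel, by a log2 fold change of 1.27, 2.58 and -2.14.

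With the slide as a block the log2 fold changes were 1.16 for Hsbp1l1, 2.28 for Cabp2 and -1.89 for Adgrv1, and no gene passed the threshold. Within slide 1, which held 2 control and 1 ethanol array, they were 1.06, 1.76 and -1.72, and within slide 3, which held 1 control and 4 ethanol arrays, 1.25, 2.72 and -2.04. Slide 2 held control arrays only. With the array's column on its slide as a covariate the values were 1.18 for Hsbp1l1, 2.48 for Cabp2 and -1.84 for Adgrv1, and no gene passed. Without the 2 arrays in slide column 1, both of ethanol mice, they were 1.27, 2.65 and -1.93, and none of these genes passed. The arrays in slide column 4 were all of control mice, so column and treatment largely went together. With 1 array left out at a time, Hsbp1l1 passed in 6 of 10 fits, not without control replicate 3, 4 or 5 or ethanol replicate 1 (1.25, 1.25, 1.25 and 1.29). Cabp2 passed only without ethanol replicate 4 or 5, and Adgrv1 only without control replicate 1 or ethanol replicate 4. With normexp background correction Cabp2 had 1.06 and did not pass.

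Genes of the 32 lists fixed before the data were examined were tested as sets with camera at a preset correlation between genes, and 11 lists passed, 3 higher and 8 lower with ethanol. None of the 11 passed with a correlation estimated from the data (smallest adjusted p = 0.54), by fry (smallest adjusted p = 0.161), or by an exact permutation of the mice's list means (smallest adjusted p = 0.254). Before adjustment the permutation p was under 0.05 for 6 of the 32 lists, among them gluconeogenesis and glycolysis (0.0238), which did not pass in camera. For called lists it was 0.0952 (stellate), 0.119 (PPARalpha), 0.198 (lymphocyte), 0.254 (macrophage), 0.27 (cell cycle) and 0.31 (acute phase). In 42 of 100 splits of the arrays into 5 and 5, the real one included, as many lists passed. The shifts below are therefore descriptions of these 10 livers.

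Fibrosis and extracellular matrix genes, among them collagens and enzymes that crosslink or cut them, fell as a set, by a mean of 0.76 on the log2 scale. All 20 measured members were lower with ethanol, none passed over all genes, and 15 passed when adjusted over the list alone. Lox, a collagen-crosslinking enzyme, had a log2 fold change of -1.55 ± 0.30 (SE), and its probe was well above background on 5 control and 2 ethanol arrays. Over the alternatives Lox ran from -1.74 to -0.375. Col1a2, a chain of type I collagen, had -1.43 ± 0.32 (SE). The smallest differences were in Acta2 (-0.13 ± 0.12, SE), Ccn2 (-0.14 ± 0.36, SE) and Tgfb1 (-0.21 ± 0.16, SE), named after their values were seen. The list's mean per mouse was 0.38 ± 0.24 (SD, n = 5) in control and -0.38 ± 0.51 (SD, n = 5) in ethanol livers, relative to the mean of the 10 mice, and all 5 ethanol mice lay below the control mean. The camera adjusted p was 2.03e-14, and with an estimated correlation the adjusted p was 0.54. The exact permutation p was 0.0317, two-sided. The shift was -0.73 with slide as a block, -1.11 within slide 1 and -0.41 within slide 3, where the list did not pass. With the array's column on its slide as a covariate it was -0.39, and without the 2 arrays in slide column 1 it was -0.48. With normexp background correction it was -0.58.

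**Figure D2:**
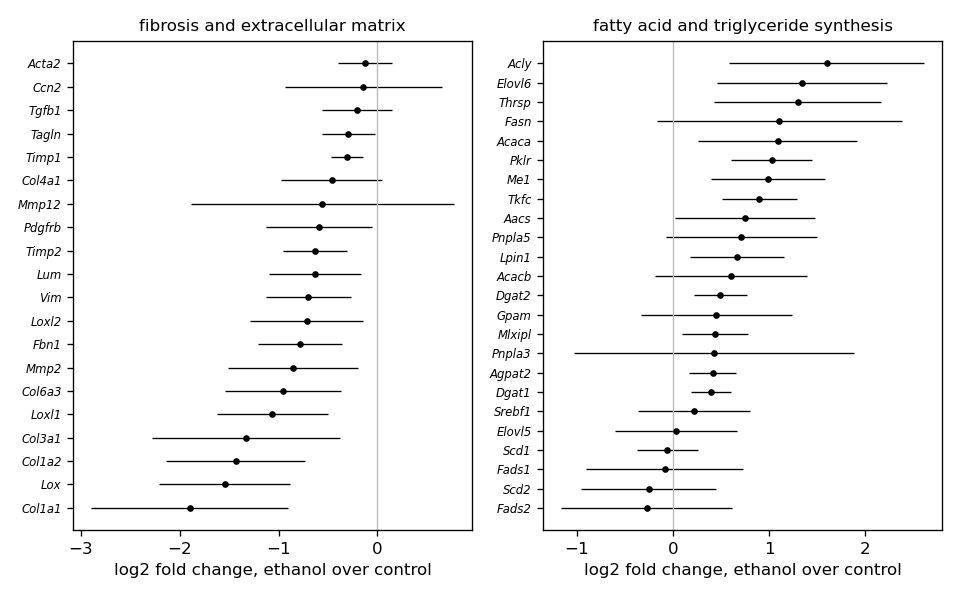
Log2 fold change of ethanol over control (horizontal axis) for each measured member of the fibrosis and extracellular matrix list and of the fatty acid and triglyceride synthesis list, with 95% confidence intervals from limma. All 20 members of the matrix list lie below 0, and 20 of the 24 members of the synthesis list lie above 0.

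Hepatic stellate cell markers, which mark the main matrix-producing cells of the liver, also fell as a set, with 11 of 13 lower and a mean log2 fold change of -0.23 (camera adjusted p = 0.00131, and adjusted p = 0.696 with an estimated correlation). Reln had a log2 fold change of -0.33 ± 0.09 (SE) and Dcn of -0.37 ± 0.11 (SE). The shift was -0.23 with slide as a block, -0.47 within slide 1 and -0.03 within slide 3. With the array's column as a covariate it was -0.08, and the list passed neither there nor within slide 3. Endothelial cell markers had a mean log2 fold change of -0.04, with 10 of 15 lower (camera adjusted p = 0.277). Their shift was -0.05 with slide as a block, -0.185 within slide 1, 0.07 within slide 3 and 0.09 with the array's column as a covariate. Their Pecam1 had 0.32 ± 0.12 (SE) and Eng -0.17 ± 0.08 (SE).

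Immune and inflammatory lists fell as sets. Interferon-stimulated genes were lower in 17 of 19 members, with a mean log2 fold change of -0.28 (camera adjusted p = 2.07e-06, and adjusted p = 0.54 with an estimated correlation). Xaf1 had -0.42 ± 0.08 (SE) and passed when adjusted over the list alone, and Isg15 had -0.33 ± 0.12 (SE). Inflammatory mediators were lower in 16 of 18 members, with a mean of -0.46 (camera adjusted p = 3.4e-05, and adjusted p = 0.54 with an estimated correlation). The chemokine receptor Ccr2 had -1.23 ± 0.27 (SE) and the chemokine Cxcl10 -0.48 ± 0.17 (SE), and Ccr2 passed when adjusted over the list alone. The exact permutation p was 0.0238 for the interferon list and 0.0397 for the inflammatory list. Acute phase genes, which the liver secretes in inflammation, had a mean of -0.18, with 18 of 24 lower (camera adjusted p = 0.00131, and adjusted p = 0.696 with an estimated correlation). Their exact permutation p was 0.31, and 3 of the 5 ethanol mice lay below the control mean. Steap4 had -0.68 ± 0.18 (SE) and Orm3 -0.83 ± 0.23 (SE), and 4 members passed when adjusted over the list alone. With slide as a block the shifts were -0.31, -0.37 and -0.15 for the 3 lists in this order. They were -0.25, -0.58 and -0.21 within slide 1 and -0.36, -0.20 and -0.11 within slide 3, where the inflammatory and acute phase lists did not pass. With the array's column as a covariate they were -0.21, -0.16 and -0.26, and the inflammatory list did not pass. Without the 2 arrays in slide column 1 the inflammatory list was at -0.28 and the acute phase list at -0.36, and without ethanol replicate 5 the acute phase list was at -0.07 and did not pass.

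Macrophage and Kupffer cell markers fell as a set by a mean of 0.37 on the log2 scale, with 15 of 20 members lower (camera adjusted p = 0.0241, and adjusted p = 0.775 with an estimated correlation). Cx3cr1 had -1.20 ± 0.41 (SE), while Clec4f, a marker of resident Kupffer cells, had 0.42 ± 0.16 (SE). The mean rested largely on 5 of the 20 members, with Gpnmb at -2.29, Trem2 at -1.11, Itgax at -1.04 and Cd14 at -0.68 beside Cx3cr1. Of the other members, Adgre1, Csf1r, C1qa, C1qb, C1qc, Cd5l and Vsig4 lay between -0.05 and 0.04. Cd68, Ctss, Ly6c2, Lyz2, Marco and Mpeg1 were lower, between -0.46 and -0.18, and Timd4 was at 0.24. These members were named after their values were seen, and none passed. The shift was -0.27 with slide as a block and -0.86 within slide 1, but 0.22 within slide 3. With the array's column as a covariate it was 0.12 and the list passed in the opposite direction, higher with ethanol. The shift was -0.09 without the 2 arrays in slide column 1 and -0.24 with normexp background correction. The list did not pass with slide as a block, within slide 3, without the arrays in slide column 1, with quantile normalization (-0.40), without slide 2 (-0.36), or without control replicate 1 (-0.32) or 5 (-0.25) or ethanol replicate 2 (-0.19) or 4 (-0.31). Lymphocyte markers fell as a set, with 12 of 15 lower and a mean of -0.22 (camera adjusted p = 0.00758, and adjusted p = 0.775 with an estimated correlation). Cd79b had -0.39 ± 0.15 (SE) and Cd74 -0.55 ± 0.26 (SE). The largest falls were in H2-Eb1 (-0.58), H2-Aa (-0.57), Cd74 and H2-Ab1 (-0.41). The T cell receptor complex genes Cd3e (0.27) and Cd3d (0.11) were higher, as was Gzma (0.02). These members were named after their values were seen, and none passed. The shift of the list was -0.21 with slide as a block, -0.14 within slide 1 and -0.28 within slide 3. It was -0.0081 with the column as a covariate, -0.02 without the 2 arrays in slide column 1 and -0.14 without ethanol replicate 2, and the list did not pass in these fits or within slide 1. Cell cycle genes fell as a set, with 16 of 20 lower and a mean of -0.43 (camera adjusted p = 0.00325, and adjusted p = 0.775 with an estimated correlation). Cdk1, the kinase that drives entry into mitosis, had -0.92 ± 0.36 (SE), with its probe well above background on 5 control and 2 ethanol arrays, and Rrm2 had 0.56 ± 0.21 (SE). Over the alternatives Cdk1 ran from -1.05 to -0.157. Here the shift was -0.48 with slide as a block, -0.66 within slide 1 and -0.33 within slide 3, but 0.08 with the column as a covariate and 0.02 without the 2 arrays in slide column 1. It was -0.22 with normexp and -0.26 without ethanol replicate 2 or without ethanol replicate 3. The list did not pass within slide 3, with the column as a covariate, without the arrays in slide column 1 or without ethanol replicate 2.

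Fatty acid and triglyceride synthesis genes rose as a set, by a mean of 0.60 on the log2 scale. Of 24 members 20 were higher, none passed over all genes, and 12 passed when adjusted over the list alone. Pklr, the liver form of pyruvate kinase, had a log2 fold change of 1.03 ± 0.19 (SE), and Tkfc, which phosphorylates glyceraldehyde in fructose metabolism, had 0.90 ± 0.18 (SE). Fasn, the fatty acid synthase, had 1.11 ± 0.57 (SE, adjusted p = 0.419), Srebf1, which encodes a transcription factor that drives this pathway, 0.22 ± 0.26 (SE), and Scd1, a desaturase, -0.06 ± 0.15 (SE). Mlxipl, another transcription factor gene of the list, named after its value was seen, had 0.44 ± 0.15 (SE) and was among the 12. The list's mean per mouse was -0.30 ± 0.18 (SD, n = 5) in control and 0.30 ± 0.55 (SD, n = 5) in ethanol livers. The camera adjusted p was 7.37e-07, and with an estimated correlation the adjusted p was 0.54. The exact permutation p was 0.0476, and all 5 ethanol mice lay above the control mean. The shift was 0.57 with slide as a block, 0.56 within slide 1 and 0.58 within slide 3. It was 0.89 with the array's column as a covariate, 0.94 without the 2 arrays in slide column 1 and 0.40 without ethanol replicate 5.

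Mitochondrial respiratory chain genes rose as a set, by a small mean of 0.17 on the log2 scale, with all 29 members higher and none past the threshold over all genes or over the list alone. Ndufs4 had 0.30 ± 0.08 (SE) and Cox5a 0.21 ± 0.07 (SE). The camera adjusted p was 1.32e-07, the adjusted p was 0.54 with an estimated correlation, and the exact permutation p was 0.0159. The shift was 0.15 with slide as a block, 0.23 within slide 1 and 0.09 within slide 3, where the list did not pass. With the array's column as a covariate it was 0.17. With quantile normalization it was 0.06, with 22 of 29 members higher, and with normexp 28 were higher. PPARalpha targets and fatty acid oxidation genes rose as a set, with 29 of 33 higher and a mean of 0.22 (camera adjusted p = 0.00547, and adjusted p = 0.775 with an estimated correlation). The members with the smallest p were the microsomal fatty acid hydroxylases Cyp4a10, with 0.83 ± 0.20 (SE), and Cyp4a31, with 0.80 ± 0.20 (SE), and both passed when adjusted over the list alone. Cyp4a14 had 0.95 ± 0.42 (SE), Ppara itself -0.08 ± 0.12 (SE), Cpt1a, which admits long-chain fatty acids to mitochondria, -0.03 ± 0.13 (SE), and the hormone gene Fgf21 0.32 ± 0.64 (SE). The shift was 0.19 with slide as a block, 0.31 within slide 1 and 0.09 within slide 3. It was 0.14 both with quantile normalization, with 23 of 33 higher, and without ethanol replicate 1, and the list did not pass in either fit or within slide 3. The shift of this list was 0.295 with the array's column as a covariate and 0.35 without the 2 arrays in slide column 1.

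**Figure D3:**
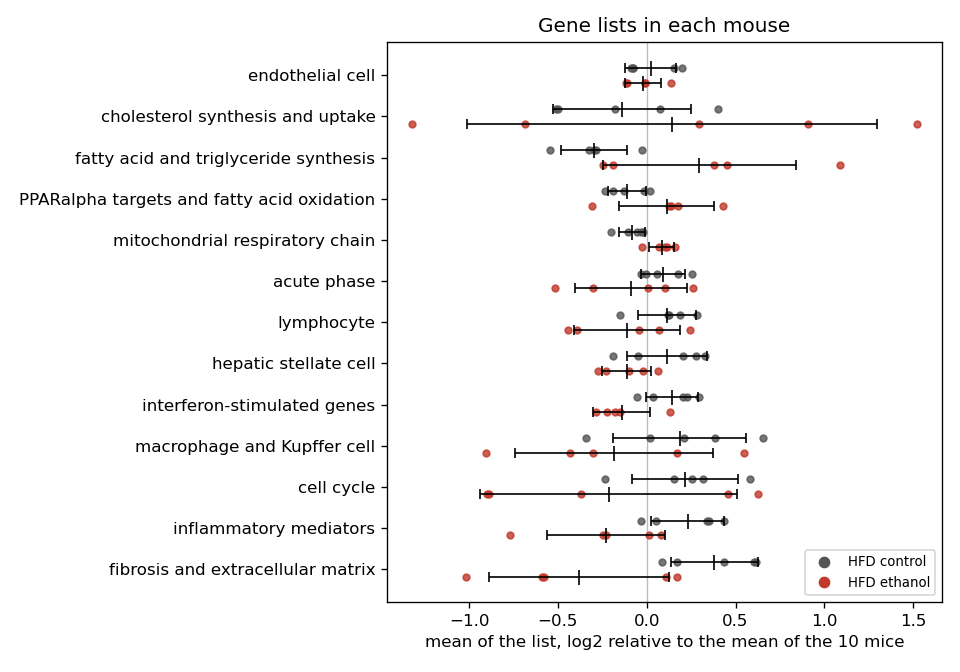
Mean of each gene list in each mouse, as log2 relative to the mean of the 10 mice (horizontal axis), for the 11 lists past the camera threshold and for the cholesterol synthesis and endothelial lists, with points for mice and bars for the mean and SD of 5 mice. Every list has overlapping groups, and the cholesterol list runs from -1.32 to 1.52 among ethanol mice.

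The other metabolic lists did not pass in the main fit, which took the 10 arrays with no covariate and the scaling and probe rules given above. Cholesterol synthesis and uptake genes had a mean log2 fold change of 0.28 with 23 of 24 members higher (camera adjusted p = 0.277), and the list's mean per mouse was -0.14 ± 0.39 (SD, n = 5) in control and 0.14 ± 1.15 (SD, n = 5) in ethanol livers. Tm7sf2 had 0.76 ± 0.33 (SE). The cholesterol list passed, higher with ethanol, with the array's column as a covariate (0.99), without the 2 arrays in slide column 1 (1.05), and without ethanol replicate 2 (0.49) or 3 (0.65). It was at 0.35 within slide 1, which held 1 ethanol array, and at 0.28 within slide 3, which held 1 control array. Without ethanol replicate 5 it was at -0.06 and did not pass. PPARgamma and lipid droplet genes had a mean of 0.08 (camera adjusted p = 0.529), and the list passed with the column as a covariate (0.325) and without the 2 arrays in slide column 1 (0.27). Among its members Cidea, a lipid droplet protein, had 1.24 ± 0.24 (SE, adjusted p = 0.159) with no overlap between groups and passed when adjusted over the list alone, Plin2 had 0.39 ± 0.17 (SE), Pparg 0.00 (-0.00072, SE 0.14), Cidec 0.05 ± 0.29 (SE) and Cd36 -0.12 ± 0.21 (SE). Gluconeogenesis and glycolysis genes had a mean of 0.19 (camera adjusted p = 0.191), with 12 of 16 higher and Gys2 at 0.25 ± 0.08 (SE). Bile acid genes had a mean of 0.07 (camera adjusted p = 0.883). Cyp8b1, which sets the cholic acid share of bile acids, had 0.83 ± 0.20 (SE) and passed when adjusted over the list alone, Slco1a4 had -0.85 ± 0.36 (SE), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, 0.80 ± 0.53 (SE). One-carbon and methionine genes had a mean of 0.17 (camera adjusted p = 0.0889), with Shmt2 at 0.26 ± 0.10 (SE) and Mthfd2 at 1.09 ± 0.46 (SE). Over the 10 arrays the list passed, higher with ethanol, with the mean of a gene's kept probes (0.18) and with normexp (0.13). Mthfd2 was at -0.59 within slide 1 and at 2.09 within slide 3.

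The list of ethanol oxidation genes had a mean log2 fold change of -0.02 and a median of 0.02, with 7 members higher and 7 lower (camera adjusted p = 0.584). Cyp2e1, the microsomal ethanol oxidase, had -0.03 ± 0.11 (SE), and its other probe had the opposite sign, at 0.05. Adh1, the main alcohol dehydrogenase, had 0.05 ± 0.16 (SE), Aldh2, the mitochondrial aldehyde dehydrogenase, -0.01 ± 0.09 (SE), and the catalase gene Cat -0.01 ± 0.13 (SE). The members with the smallest p were Acss1, with -0.79 ± 0.31 (SE), and Aldh3a2, with -0.23 ± 0.12 (SE). CAR and PXR target genes of drug metabolism had a mean of 0.07 while camera's direction was lower (camera adjusted p = 0.63). Sult1e1, an estrogen sulfotransferase, had -1.09 ± 0.22 (SE) and passed when adjusted over the list alone, Nr1i2 had 0.36 ± 0.14 (SE) and Cyp2b10 0.70 ± 0.46 (SE). NRF2 targets and glutathione genes had a mean of -0.08 (camera adjusted p = 0.277), with Gsta2 at -0.75 ± 0.30 (SE) and Gstm2 at -0.82 ± 0.39 (SE). The list passed, lower with ethanol, with slide as a block (-0.22), and was at -0.31 within slide 1 and -0.14 within slide 3. It had the opposite sign with the array's column as a covariate (0.09) and without the 2 arrays in slide column 1 (0.10). The unfolded protein and integrated stress response list had a mean of 0.16 (camera adjusted p = 0.331), with Psat1 at 1.10 ± 0.47 (SE) and Trib3 at 0.50 ± 0.23 (SE). Within slide 1 the list was at -0.33, Psat1 at -0.63 and Trib3 at -0.42. Within slide 3 they were at 0.37, 1.76 and 0.625. The iron hormone gene Hamp had 0.48 ± 1.10 (SE).

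Lists for liver zones, sex-biased genes and the clock did not pass either in the main fit. Pericentral hepatocyte genes had a mean of 0.02 with camera's direction lower (camera adjusted p = 0.584). Their Rhbg, an ammonium transporter, had 0.70 ± 0.10 (SE, adjusted p = 0.0834) and passed when adjusted over the list alone, and Lect2 had -0.40 ± 0.14 (SE). Periportal genes had a mean of -0.09 (camera adjusted p = 0.338), with Apoc2 at -0.33 ± 0.19 (SE) and Serpina1c at 0.18 ± 0.12 (SE). Male-biased genes had a mean of 0.26 (camera adjusted p = 0.295), with Nudt7 at 0.56 ± 0.25 (SE) and Cyp4a12a at 0.60 ± 0.28 (SE). Female-biased genes had a mean of 0.44 (camera adjusted p = 0.211). The female-biased list passed, higher with ethanol, with array weights (0.61) and without the 2 arrays in slide column 1 (0.74). It was at 0.89 within slide 1, which held 1 ethanol array, and at -0.40 within slide 3, which held 1 control array. Among its members Sult3a1 had 2.49 ± 0.93 (SE), with its probe well above background on 1 control and 4 ethanol arrays, and Cyp2c69 had 0.27 ± 0.10 (SE). Circadian clock genes had a mean of 0.20 (camera adjusted p = 0.4), with Nr1d2 at 0.24 ± 0.16 (SE).

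Markers of other cell types that a liver piece can hold did not pass in the main fit. With no filter on dim probes the cholangiocyte list passed, lower with ethanol (-0.35). The cholangiocyte and neutrophil lists were at -0.66 and -0.41 within slide 1 and at -0.12 and 0.02 within slide 3. Cholangiocyte markers had a mean log2 fold change of -0.34 (camera adjusted p = 0.131), with Sox9 at -0.66 ± 0.26 (SE) and Spp1 at -1.08 ± 0.57 (SE). Neutrophil markers had a mean of -0.14 (camera adjusted p = 0.346), with S100a8 at -0.72 ± 0.26 (SE) and S100a9 at -0.51 ± 0.19 (SE). Erythroid markers had a mean of -0.07 (camera adjusted p = 0.529), with Ermap at 0.11 ± 0.13 (SE) and Hba-a2 at -0.22 ± 0.27 (SE). Adipocyte markers had a mean of -0.33 (camera adjusted p = 0.529), with Fabp4 at -0.61 ± 0.38 (SE) and Lpl at -0.46 ± 0.33 (SE). Pancreatic acinar markers had a mean of 0.14 (camera adjusted p = 0.416), with Ctrb1 at 0.34 ± 0.20 (SE) and Clps at 0.11 ± 0.08 (SE). Skeletal muscle markers had a mean of 0.07 and a median of -0.03 (camera adjusted p = 0.584). There Tnnc2 had 0.41 ± 0.12 (SE) and passed when adjusted over the list alone, and Tnnt3 had 0.29 ± 0.12 (SE).

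Of the 84 genes that the rule for named genes took, 3 passed the threshold over all genes, and the adjusted p of the other 81 ran from 0.0834 to 0.998. With slide as a block all 84 kept the sign of their log2 fold change, and 73 kept it within slide 1 and 75 within slide 3. Among the 32 lists these counts were 30, 29 and 25. The sign was kept in all 3 of these fits by 64 genes and 22 lists. Most of the 84 genes were taken by their p in these same arrays, so the kept signs are not separate evidence across slides. Probes for members of the Cyp2c, Cyp4a, Orm, Gstm and Hba families can bind transcripts of close relatives, so their values are uncertain as to the member.

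The correlations between arrays overlapped within and across groups. Over the tested genes they ran from 0.983 to 0.995 within control, from 0.978 to 0.993 within ethanol and from 0.969 to 0.993 across groups. The first principal component held 39.5% of the variance, with ethanol replicates 2 and 3 at 41 and 45.4 and control replicate 1 at -40 at the ends. It followed the array's column on the slide over the 10 arrays (Pearson r = -0.838, permutation p = 0.00259, adjusted over 4 relations 0.0104; Spearman rho = -0.813, permutation p = 0.00657, adjusted 0.0263). Without the 2 arrays farthest from the median column r was -0.548. The permutations took no account of group, though column 1 held ethanol mice only and column 4 control mice only. No slide held the 6 arrays needed for a correlation, so values are given within slides. In slide 3 the component was 41 and 45.4 in column 1, 1.51 and -15.6 in column 2 and -11.6 in column 3. In slide 1 it was 10.4 in column 3 and -20.7 and -17.4 in column 4, and in slide 2 it was 6.97 in column 3 and -40 in column 4.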

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

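Among 232 groups of 5 mice, 1 for each named gene or list and each treatment, 14 held a mouse whose gap to its nearest neighbour was large for the range of its group, where chance gives about 12. Of the 14, 7 were in ethanol replicate 3, whose array lay in column 1 of its slide. Values are log2 differences between that mouse and the mean of the other 4 mice of its group. In ethanol replicate 3 they were -1.82 for Slco1a4, -1.02 for Cd36, -2.18 for Cyp2b10 and -1.9 for Cyp4a14. In the same mouse they were -0.46 for the ethanol oxidation list, -0.732 for the circadian clock list and -1.52 for the female-biased list. Ethanol replicate 2 lay apart for Steap4 at 0.763. Control replicate 3 lay apart at -0.581 for Trib3, -0.132 for Rrm2, -0.388 for Cd36 and -0.432 for the NRF2 and glutathione list. Control replicate 1 lay apart at 0.711 for Ccr2 and 0.0494 for Adh1.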

How the results depend on the processing

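The 3 genes and 11 lists past the threshold were recomputed under 21 alternatives, of which 5 were chosen after seeing the data (normexp on median signals, a floor of 1, the slide column as a covariate, the fit without the arrays in slide column 1, and the exact permutation of list means), and without each array in turn. Not every alternative applies to each result. Normexp on mean signals was not run. Hsbp1l1 passed under 9 of 17 alternatives, Adgrv1 under 9 of 17 and Cabp2 under 7 of 16, and none of the 3 changed sign (0.914 to 1.32, -2.26 to -1.72 and 1.06 to 2.72). Their adjusted p ran up to 0.999 in limma. The counts of genes higher and lower were 2 and 1 with quantile normalization, with the authors' deposited values, with the mean of a gene's probes, with a floor of 1 and with each probe tested separately. They were 1 and 1 over probes well above background on all arrays, 8 and 4 with slide as a random block (where the correlation within slides was estimated at -0.128, below 0, so that this fit takes arrays of 1 slide as less alike than arrays of different slides), 5 and 2 with trend and robust eBayes, 9 and 6 with array weights, 4 and 3 with normexp, and 2 and 0 without the arrays in slide column 1, where the 2 genes were Adcy10 and Cidea. With limma they were 0 and 0 with no filter on dim probes (22910 genes tested, 2406 at an unadjusted p under 0.05), with slide as a fixed block (806), without the slide of control arrays only (1247), within slide 1 (2094), within slide 3 (677) and with the slide column as a covariate (866). The cause was not tested, except that no filter meant more genes tested and that the fits within slides, without a slide or without the arrays of column 1 had fewer samples. Within slides, 1 group held a single array, assumed to vary like the others. The signal over background limits dim genes such as Cabp2, which was well above background on 4 of 5 control arrays.

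The replicate numbers that the labels give both groups were not taken to pair the mice, since not every pair of the same number deviated together. Deviations from the group means correlated at 0.324, 0.148, 0.311, 0.0642 and -0.11 for numbers 1 to 5, and 1 of 5 control arrays correlated best with its own number. A fit with the replicate number as a block gave 0 genes higher and 0 lower in limma, with 2443 at an unadjusted p under 0.05, and 3 lists up and 8 down.

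The counts of lists up and down stayed at 2 to 4 and 7 to 9 except as follows. They were 6 and 12 within slide 1, 2 and 2 within slide 3, 6 and 5 with the slide column as a covariate, and 6 and 6 without the arrays in slide column 1. They were 0 and 0 with an estimated correlation, by fry and by the exact permutation of mice, and the cause was not tested. Of the 21 other lists 13 passed in some fit, with 23 values under alternatives and 12 without 1 array. With the slide column as a covariate these were cholesterol synthesis (0.992), PPARgamma and lipid droplet (0.325), pericentral (-0.173) and CAR and PXR targets (-0.145). Without the arrays in slide column 1 they were cholesterol synthesis (1.05), PPARgamma (0.273), female-biased (0.744) and periportal (-0.283). Within slide 1 they were cholesterol synthesis (0.348), stress response (-0.327), NRF2 (-0.311), one-carbon (0.154), female-biased (0.892), endothelial (-0.185), cholangiocyte (-0.662) and neutrophil (-0.414), and within slide 3 the stress response (0.371). The female-biased list passed with array weights (0.614), and NRF2 with slide as a block (-0.217) and without slide 2 (-0.169). One-carbon passed with the mean of probes (0.182) and normexp (0.133), and cholangiocyte with no filter (-0.354). Without control replicate 2, 3 or 5 the lists were female-biased (0.624), NRF2 (-0.17) with male-biased (0.411), and cholangiocyte (-0.409). Without ethanol replicate 1 it was one-carbon (0.242), without replicate 2 cholesterol (0.492), without replicate 3 cholesterol (0.651), PPARgamma (0.187) and female-biased (0.742), and without replicate 5 NRF2 (-0.183), one-carbon (0.222) and cholangiocyte (-0.486). Of the 11 lists 9 never changed sign. Without 1 array the counts ran from 0 to 3 genes higher, 0 to 4 lower, 3 to 6 lists up and 5 to 9 down. No gene passed in limma without control replicate 3, 4 or 5 (2274, 1493 and 1475 at an unadjusted p under 0.05) or without ethanol replicate 1 (2066). The counts higher and lower were 1 and 1 without control replicate 1, 2 and 1 without control replicate 2, 1 and 0 without ethanol replicate 2, 3 and 0 without ethanol replicate 3, 3 and 4 without ethanol replicate 4, and 3 and 0 without ethanol replicate 5. Lists down numbered 5 without ethanol replicate 2, and lists up 6 without ethanol replicate 3.

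Over the alternatives, 42 of 1424 values of named genes and 41 of 607 values of lists had the opposite sign, as follows, and the cause was not tested. With quantile normalization Adh1 was at -0.03 and Cidec at -0.0775. The CAR and PXR target drug metabolism list was at -0.000394, pericentral hepatocyte at -0.0521 and skeletal muscle at -0.00308. With no filter on dim probes the skeletal muscle list was at -0.00952. With the mean of a gene's kept probes Cyp2e1 was at 0.00848. With slide as a fixed block the ethanol oxidation list was at 0.000199 and the pericentral hepatocyte list at -0.00525. With slide as a random block Aldh2 was at 0.00536 and Pparg at 0.0194. Within slide 1 Psat1 was at -0.633, Trib3 at -0.421, Mthfd2 at -0.588, Cyp4a12a at -0.039, Lect2 at 0.0768 and Pecam1 at -0.101. Cyp2e1 was at 0.0615, Aldh2 at 0.0053, Pparg at 0.0361, Cd36 at 0.00782 and Fgf21 at -0.331. The ethanol oxidation list was at 0.0723, unfolded protein and integrated stress response at -0.327 and periportal hepatocyte at 0.00904. Within slide 3 Acss1 was at 0.0919, Cyp2c69 at -0.0687, Serpina1c at -0.178, S100a8 at 0.0854, Lpl at 0.205 and Clps at -0.0478. Cpt1a was at 0.0781, Cyp2b10 at -0.184 and Hamp at -0.0762. The CAR and PXR target drug metabolism list was at -0.0833, female-biased at -0.401, pericentral hepatocyte at -0.161, macrophage and Kupffer cell at 0.217, endothelial cell at 0.0657 and neutrophil at 0.0162. The pancreatic acinar cell list was at -0.0362. With array weights Cyp2e1 was at 0.0131 and Pparg at 0.0142. The ethanol oxidation list was at 0.0116. With normexp on median signals the pericentral hepatocyte list was at -0.0137. With the slide column as a covariate Serpina1c was at -0.00364, Cd74 at 0.00801, Hba-a2 at 0.155, Fabp4 at 0.128, Scd1 at 0.0851 and Cpt1a at 0.0652. Pparg was at 0.067, Cd36 at 0.179 and Hamp at -0.578. The ethanol oxidation list was at 0.0844, CAR and PXR target drug metabolism at -0.145, bile acid synthesis and transport at -0.0935, NRF2 targets and glutathione at 0.088, male-biased at -0.174 and cell cycle at 0.0788. The pericentral hepatocyte list was at -0.173, macrophage and Kupffer cell at 0.124, endothelial cell at 0.0882, erythroid cell at 0.109, pancreatic acinar cell at -0.104 and skeletal muscle at -0.012. Without the arrays in slide column 1 Hba-a2 was at 0.0515, Scd1 at 0.0982, Cpt1a at 0.0156, Pparg at 0.102, Cd36 at 0.142 and Hamp at -0.658. The ethanol oxidation list was at 0.086, CAR and PXR target drug metabolism at -0.0957, bile acid synthesis and transport at -0.0703, NRF2 targets and glutathione at 0.103, male-biased at -0.102 and cell cycle at 0.0224. The pericentral hepatocyte list was at -0.106, endothelial cell at 0.0176, erythroid cell at 0.00915, pancreatic acinar cell at -0.0146 and skeletal muscle at -0.0314.

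Without 1 array at a time, some values crossed 0. Cpt1a ran from -0.127 to 0.044, Pparg from -0.0923 to 0.0734, Hamp from -0.0373 to 1.27, Cyp2e1 from -0.103 to 0.0207 and Aldh2 from -0.0626 to 0.025. Cidec ran from -0.139 to 0.297, Cat from -0.114 to 0.071, Adh1 from -0.0452 to 0.19, Scd1 from -0.15 to 0.0265 and Cd36 from -0.212 to 0.0851. Fgf21 ran from -0.323 to 0.643. The CAR and PXR target drug metabolism list ran from -0.0419 to 0.155, pericentral hepatocyte from -0.0428 to 0.0855, endothelial cell from -0.0832 to 0.000745 and erythroid cell from -0.182 to 0.0272. The periportal hepatocyte list ran from -0.184 to 0.0101, ethanol oxidation from -0.0473 to 0.0756 and cholesterol synthesis and uptake from -0.0594 to 0.651.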

Other observations

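At a wider threshold, an adjusted p of 0.1 in limma, 13 genes passed, 9 higher and 4 lower with ethanol. This threshold and the genes below were chosen after their values were seen. Besides Hsbp1l1, Cabp2, Adgrv1 and Rhbg, they held Pdhb, a subunit of the pyruvate dehydrogenase complex, with a log2 fold change of 0.84 ± 0.13 (SE), and Pank1, a kinase at the start of coenzyme A synthesis, with 0.59 ± 0.08 (SE). Slc9a5, a sodium-proton exchanger, had 0.79 ± 0.12 (SE) and Oog2 0.66 ± 0.11 (SE). Atp8b5, a phospholipid-transporting ATPase, had -1.51 ± 0.22 (SE), and Pros1, which encodes the anticoagulant protein S, had -0.48 ± 0.08 (SE). Adcy10 was not well above background in control livers and was at least 1.72-fold higher with ethanol. Gm10433 was at least 1.65-fold higher and Rbm24 at least 2.21-fold lower, each against a group where it was not well above background. These bounds set the mean of the brighter group against the lowest signal of a probe well above background on each dim array, or the probe's own signal where higher. With slide as a block the values were 0.96 for Pdhb, 0.69 for Pank1, 0.84 for Slc9a5, 0.56 for Oog2, -1.24 for Atp8b5 and -0.45 for Pros1.

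The tests on fibrosis and cholesterol genes were chosen after the results were seen, and those on spike-ins and on splits of the arrays before. Fibrosis and extracellular matrix genes were lower with ethanol by -0.762 in the list's mean per mouse (95% interval -1.34 to -0.181). The list fell further than the endothelial list by -0.718 (-1.22 to -0.221) and than the stellate list by -0.535 (-0.94 to -0.13). These contrasts were picked once the shifts of the lists were known, and neither slide nor column was in their fit. With the column as a covariate the endothelial list was at 0.0882 and the stellate list at -0.0803. The contrasts therefore cannot decide on a lower share of non-hepatocyte cells, which stays open. A slide batch stays open, as the difference with slide as a block was -0.731 with an interval of -1.66 to 0.197. With the array's column as a covariate the difference was -0.389 (-1.03 to 0.25), so a difference that goes with the column stays open. For 7 spike-ins the move over the columns, with 2 standard errors, was at most 0.15. This argues against hybridisation or scanning as the source of a move of 0.5 or more between bright probes. Each spike-in was centred on the spike-in mean of its array and was well above background on all arrays. A shift shared by probes, or one limited to dim probes, could therefore not show. Steps before the spike-ins were added and differences between the mice stay open and were not tested. An effect of ethanol on matrix genes remains a hypothesis beside these.

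Cholesterol synthesis genes spread widely among ethanol mice. The list's mean was 0.909, -0.687, -1.32, 0.293 and 1.52 in ethanol replicates 1 to 5 and 0.0761, -0.178, -0.498, 0.399 and -0.51 in control replicates 1 to 5. The SD among ethanol mice was 2.97 times that among control mice, and 1.77 times once the linear trend with the array's column was taken out, so that a difference that goes with the column cannot be told apart from ethanol with so few arrays per column. The spike-in values argue, with the limits given above, against hybridisation or scanning as its source here too, and leave open earlier steps and the mice themselves. An equal spread in both groups is not excluded (exact permutation p = 0.0794, adjusted over the lists 0.677).

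The first principal component followed the array's column on its slide. A column effect on hybridisation or scanning that moves bright probes apart by 0.5 or more is argued against by 7 spike-ins added to every sample. Their largest move over the columns was -0.0843 on the log2 scale, under the bound of 0.5 set beforehand. Small moves along the columns were seen, with -0.0843, -0.0562 and 0.0685 each beyond 2 standard errors. The groups were not spread evenly over the columns, as column 1 held ethanol mice only and column 4 control mice only. Column and treatment therefore largely went together. A difference between the mice themselves, an effect of ethanol included, stays open and was not tested.

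Of the 126 distinct splits of the arrays into 5 and 5, 100 were drawn, the real one included. A count of 2 genes or more in 1 direction came in 3 splits, and a count of 1 or more in 4. Arrays could not be exchanged freely between slides, which the groups shared unevenly. These splits therefore cannot exclude chance for the real counts of 2 genes higher and 1 lower. For the 2002 genes at an unadjusted p under 0.05 chance cannot be excluded, since 6 splits gave as many, and up to 3603 in another split. The highest count past the threshold in 1 direction in another split was 618. The split of control replicates 1, 4 and 5 and ethanol replicates 1 and 5 from the rest called 831 genes in all, many times the real 3, which points to a structure of the samples that partly follows the slide column. With slide as a block no gene passed in limma, with 806 at an unadjusted p under 0.05. For lists chance cannot be excluded, since 92 splits gave as many as the 3 lists up and 36 as many as the 8 lists down, with 13 as the highest other count.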
